A study of Mus musculus with 36 samples.

How the data were processed

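Whole-brain RNA of male C57BL/6J mice was measured by RNA sequencing in 36 libraries, made with a TruSeq kit (version 2 of the RNA kit) that does not record the strand, so reads of genes that overlap on opposite strands cannot be told apart. Per the labels, the authors used Salmon 1.1.0, R 3.6.2 and DESeq2 1.26.0 with genome build GRCm38, and the annotation release and any filter on genes are not given in the sources used here. The deposited signal values are estimated gene counts that the authors divided by normalization factors computed over all 36 libraries together. The values were checked for this: 0.748% of them were whole, all of which were 0, and the median ratio of a library to the geometric mean of each gene was 1.01 in every library. Whole reads were not recovered, so the depth per library is unknown, no counting interval is given, and the spread between libraries is the only measure of precision.

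The table held 19164 genes, of which 19150 identifiers matched the mouse GENCODE annotation of GRCm38 and 14 did not. Of the symbols, 22 were shared by several identifiers. All 36 columns were matched to samples by their names, and age and genotype were taken from the labels. As a check of the labelled sex, all 4 Y-linked genes looked at were above 10 normalized counts in 36 of 36 libraries. The labels name separate samples and do not say whether any mice shared a litter.

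The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The plan covered both count tables and normalized values, and because the values were normalized the branch for normalized values was used. Genotypes were compared within each age, wild-type ages were compared with each other, and the genotype difference was compared between ages in a model of the 6 groups. Values were taken to log2 after adding 1. Genes were kept with a value of at least 10 in as many libraries as the smaller group has. Differences were tested with limma 3.58.1 in R 4.3.3, with the trend and robust options, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 95% intervals of the Myt1l fold used limma's moderated error. Adjusted p values that are given without another name come from limma or from its set test camera.

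In all, 32 gene lists were written from general knowledge of brain cell types and pathways, and 29 had at least 5 tested members at each age. The MYT zinc-finger family, the anterior pituitary and the sex-linked genes had too few. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of an age, and beside it with camera at an estimated correlation and with fry, which asks whether a set moves on balance in 1 direction. Each gene of a list was also adjusted over the list alone. The list called with an estimated correlation, progenitors and Notch signalling at P3, was also the only list that fry called. A list's mean log2 value per library was compared by an exact two-sided permutation test. Maturation sets held the 300 genes with the largest change in each direction between wild-type ages other than the tested one.

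Named genes were to be Myt1l and, among genes that passed with a mean of at least 20 and a symbol that is not a clone or predicted name, the 12 with the largest change in each direction. Where fewer than 5 genes passed, the 10 genes of smallest p were named with their values. For a list, the 4 members of smallest p were eligible, and the text gives a part of them. A result for 1 gene is not reported here.

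The procedure was tested on simulated data with 1 measured spread per gene, averaged over the 6 groups, and no shared variation between genes. Differences in spread between the ages thus do not enter the recovered counts. Of 100 genes given a log2 change of 0.5, it recovered 70 at P3, 55 at P21 and 53 at P56, and of those given a change of 1 it recovered 91%, 84.8% and 88%. The alternatives tried were quantile normalization, a common library total, no filter, a filter at 50, limma without the trend, library quality weights, added values of 0.5 and 8, a fit of all libraries, a block for the replicate number, a block for the P21 description prefix, an estimated correlation, maturation sets of 100 and 1000 genes, and each library left out. After the data were seen, 4 more were added, which left out libraries beyond 2 SD, removed a trend on gene length, left out the P3 libraries with description numbers 1 to 3, and used the P21 prefix as a block in the list tests.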

Results

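The study measured gene expression by RNA sequencing in whole brains of male C57BL/6J mice, labelled wild-type or Myt1l heterozygote, on postnatal days 3, 21 and 56 (P3, P21 and P56). The labels list 36 samples, with 8 per genotype at P3 and 5 per genotype at P21 and at P56. They give no allele, litter or sequencing batch, so the groups are called wild-type and heterozygote-labelled here. Normalized counts added up to between 31707059 and 33555147 per library at P3, 34492184 and 37840500 at P21, and 34475862 and 38202024 at P56. These are totals after scaling, and the depth of sequencing is unknown. Of the libraries, P3 wild-type replicate 1 lay -2.65 SD from its age's mean on principal component 1. P21 heterozygote-labelled replicate 3 lay 2.16 SD away on component 1, and P21 wild-type replicate 5 lay -2.61 SD away on component 2. At P56 no library lay beyond 2 SD on either component.

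Myt1l, a zinc-finger transcription factor of neurons and the gene named in the genotype label, was higher in the heterozygote-labelled brains at P3. Its normalized count was 15659 ± 934 (SD, n = 8) in these libraries and 11235 ± 538 (SD, n = 8) in wild-type, a fold of 1.39 with a 95% interval of 1.32 to 1.48. The lowest heterozygote-labelled library, at 14184, lay above the highest wild-type library, at 12051. An exact two-sided permutation test over 12870 assignments gave p = 1.55e-04, the smallest it can give, and limma gave an adjusted p of 2.53e-06 for a log2 fold change of 0.48 (SE 0.040). At P21 the counts were 7742 ± 511 and 7210 ± 620 (SD, n = 5 each), a fold of 1.08 with a 95% interval of 0.968 to 1.19 and an exact permutation p of 0.175. At P56 they were 6536 ± 566 and 6053 ± 1190 (SD, n = 5 each), a fold of 1.09 with a 95% interval of 0.921 to 1.29 and an exact permutation p of 0.373. None of the 3 ages showed a lower count of this gene in the heterozygote-labelled libraries. With the trend on gene length removed, the log2 difference was 0.47 at P3. It went from 0.10 to 0.018 at P21 and from 0.13 to 0.032 at P56. Without P56 wild-type replicate 3 the P56 difference was 0.24. Myt1l (ENSMUSG00000061911) is a protein-coding gene on chromosome 12 from 29528384 to 29923213 in GRCm38. The gene-level value adds all transcripts and does not tell a mutant from a normal one. In wild-type brains Myt1l fell by 0.64 on the log2 scale from P3 to P21 (SE 0.0539, adjusted p = 7.83e-09), and its log2 difference from P21 to P56 was -0.27 (SE 0.114, adjusted p = 0.155).

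**Figure D1:**
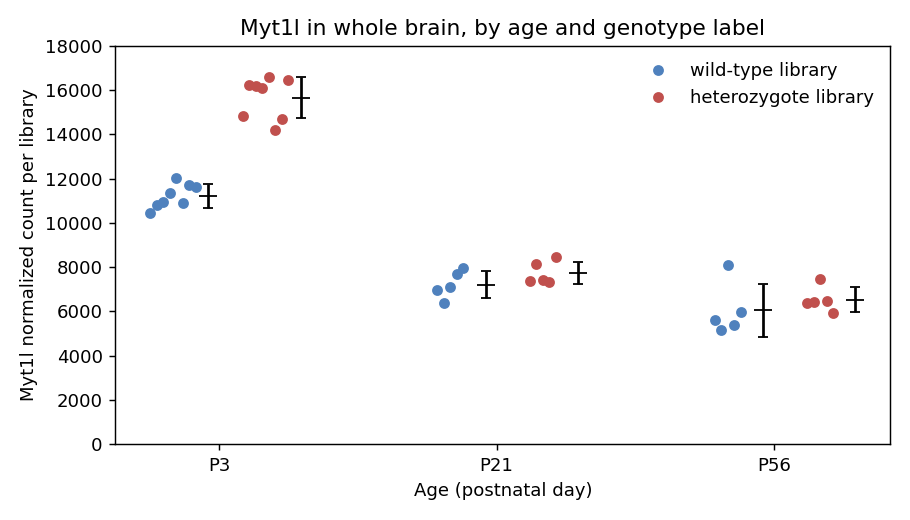
Normalized count of Myt1l per library (vertical axis, from 0) by postnatal age and genotype label. Points are libraries and bars are the mean ± SD of 8 libraries per group at P3 and 5 at P21 and P56. At P3 the heterozygote-labelled libraries sit between 14184 and 16585 and the wild-type ones between 10450 and 12051, and at the other ages the ranges overlap.

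The wild-type libraries give the developmental background against which the genotypes were compared. From P3 to P21, 25 of 25 myelin and oligodendrocyte genes rose, with a median log2 change of 4.44. Ermn, a cytoskeletal protein of myelinating oligodendrocytes, went from 68.8 ± 19.6 (SD, n = 8) to 3496 ± 709 (SD, n = 5; adjusted p = 7.52e-14). Of the cell cycle genes 38 of 40 fell, with a median of -2.67, among them the proliferation marker Mki67, from 2235 ± 328 (SD, n = 8) to 135 ± 16.1 (SD, n = 5; adjusted p = 2.99e-15). Of the immature neuron and axon growth genes 39 of 41 fell, with a median of -1.48. The microtubule-associated protein gene Dcx fell by 4.64 on the log2 scale (SE 0.0830, adjusted p = 1.15e-16). Genes of mitochondrial oxidative phosphorylation rose in 74 of 74 cases and microglial genes in 25 of 25, with medians of 0.78 and 1.38. Of the presynaptic genes 30 of 40 rose and 7 fell, and Snap25, a SNARE protein of vesicle fusion, rose from 13538 ± 2747 (SD, n = 8) to 81312 ± 9261 (SD, n = 5; adjusted p = 3.67e-12). Of the autism-risk chromatin and transcription regulators 44 of 50 fell, with a median of -0.55.

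From P21 to P56 the wild-type changes were fewer. Myelin genes fell in 15 of 25 cases, with a median of -0.81. Immature neuron genes fell in 17 of 41 cases, and Marcksl1 fell by 1.33 on the log2 scale (SE 0.115, adjusted p = 3.35e-05). The haemoglobin gene Hba-a1 fell by 2.56 on the log2 scale (SE 0.294, adjusted p = 2.95e-04). In all, 6863 genes rose and 7201 fell of 17821 tested from P3 to P21, and 628 rose and 1060 fell of 17184 tested from P21 to P56. The second count fell to 874 without P21 wild-type replicate 3 and was 2999 with library quality weights. Age cannot be told apart from a sequencing batch, which the labels do not give.

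The comparison of genotypes at P3 asks which genes differ in the brain soon after birth. Neural progenitor and Notch signalling genes were higher in the heterozygote-labelled libraries in 25 of 31 cases, with a median log2 difference of 0.063. Among them were Vim, an intermediate filament of radial glia, at 5214 ± 476 against 4697 ± 479, and the Notch receptor gene Notch1 at 2242 ± 194 against 2065 ± 197 (SD, n = 8 each). The transcription factor gene Pax6 was at 1083 ± 107 against 959 ± 184 and the Notch ligand gene Dll3 at 205 ± 21.3 against 184 ± 26.0 (SD, n = 8 each). As a set these genes rose relative to other genes (camera adjusted p = 2.44e-04), and the call held with an adjusted p of 0.0238 with an estimated correlation. The mean log2 value of the list per library gave an exact two-sided permutation p of 0.00109, not adjusted for the number of lists. No member passed by itself, with 0 of 31 genes adjusted over the list alone and 0 over all genes tested.

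Cell cycle genes were higher at P3 in 37 of 40 cases, with a median log2 difference of 0.11 and a camera adjusted p of 5.52e-09, and an adjusted p = 0.906 with an estimated correlation. Cenpf, a kinetochore protein, was at 838 ± 186 against 676 ± 110, and Top2a, the topoisomerase of dividing cells, at 1813 ± 172 against 1625 ± 193 (SD, n = 8 each). Presynaptic genes were lower in 38 of 40 cases, with a median of -0.076 and a camera adjusted p of 4.30e-06, and an adjusted p = 0.953 with an estimated correlation. Their median was -0.040 without P3 wild-type replicate 1, -0.038 without wild-type replicate 2 and -0.027 (adjusted p = 0.0161) without the 3 libraries with description numbers 1 to 3. The calcium sensor gene Doc2b was at 2296 ± 116 against 2523 ± 245 and the active-zone gene Erc2 at 5975 ± 219 against 6382 ± 526 (SD, n = 8 each). The autism-risk chromatin list was higher in 35 of 50 cases, with a median of 0.035 and a camera adjusted p of 0.0461, and an adjusted p = 0.953 with an estimated correlation. That call ended without any 1 of P3 heterozygote-labelled replicates 3, 4, 5 and 8 or wild-type replicates 1, 2 and 6, with adjusted p up to 0.753 (without wild-type replicate 1, median 0.0076), and with the length trend removed (median 0.022, adjusted p = 0.152). Without the libraries with description numbers 1 to 3 its median was 0.0062 (adjusted p = 0.690). In these 3 lists 0 genes passed adjusted over the list alone and 0 over all genes. Of 100 splits of the P3 libraries into equal groups, the real one included, 95 called at least as many lists as the 4 called here.

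Gene by gene, Myt1l was the only one of 17371 genes that passed at P3 by limma with the trend, and 875 genes had an unadjusted p below 0.05 where chance gives 869. The 10 genes next in p had adjusted values of 0.808 to 0.903. Grin3a, an NMDA receptor subunit, was at 5637 ± 288 against 6272 ± 246 (SD, n = 8 each). It was the 1 of 50 postsynaptic genes that passed adjusted over the list alone (adjusted p = 0.0154), against 0 over all genes. At P3 Spata32 was at 18.7 ± 2.01 against 28.4 ± 3.75 (SD, n = 8 each) and passed with an adjusted p of 0.0183 in limma without the trend. Lars, the cytosolic leucyl-tRNA synthetase, was at 2318 ± 128 against 2046 ± 112, and Nrg3, a ligand of the receptor ERBB4, at 1522 ± 43.6 against 1672 ± 68.9 (SD, n = 8 each). The genotype ranges of these last 3 genes did not overlap. The other 6 were Ptpru, Svil and Pold1, with log2 differences of 0.20, 0.21 and 0.31, and Slc25a1, Lmo4 and Tspan17, with -0.15, -0.14 and -0.32.

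At P21 the same question was put to brains of the juvenile period. Cytosolic ribosomal protein genes were lower in the heterozygote-labelled libraries in 77 of 79 cases, with a median log2 difference of -0.21, and nuclear genes of oxidative phosphorylation in 73 of 74, with -0.20. With the trend on gene length removed these medians were -0.12 and -0.097, and without libraries beyond 2 SD -0.16 and -0.12. Heterozygote-labelled replicate 3, the library beyond 2 SD on component 1, had the lowest mean log2 value of both lists, -0.42 and -0.44 from the wild-type mean. Rps2 was at 9587 ± 1354 against 11834 ± 723 and Rplp1 at 8163 ± 1370 against 10119 ± 456 (SD, n = 5 each). The cytochrome c oxidase gene Cox8a was at 10621 ± 1288 against 13197 ± 972 and Cox6a1 at 7861 ± 1292 against 9706 ± 530 (SD, n = 5 each). Adjusted over the list alone, 56 of the 79 ribosomal and 35 of the 74 oxidative phosphorylation genes fell, and 0 did over all genes tested. Camera gave adjusted p values of 1.30e-22 and 4.58e-22, and an adjusted p = 0.866 with an estimated correlation for both lists. The mean log2 values of the lists per library gave an exact two-sided permutation p of 0.0317 for each, not adjusted for the number of lists.

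Another 7 lists were called at P21 with the preset correlation, and with an estimated correlation their adjusted p values were 0.866 to 0.988. The mean log2 values of these lists per library gave exact two-sided permutation p values of 0.0794 to 0.373. Blood cell genes were lower in 9 of 10 cases, with a median log2 difference of -0.84, or -0.38 with the description prefix as a block, and 5 of the 10 fell adjusted over the list alone against 0 over all genes. The haemoglobin gene Hbb-bs was at 10027 ± 3146 against 20185 ± 8210 and Alas2, the haem synthesis enzyme of red cells, at 355 ± 121 against 836 ± 436 (SD, n = 5 each). Microglial genes were lower in 24 of 25 cases, with a median of -0.17, including Tyrobp at 315 ± 60.2 against 378 ± 56.3 (SD, n = 5 each). Camera adjusted p values were 0.00198 for blood and 0.00477 for microglia. Immediate-early genes were lower in 21 of 24 cases (median -0.14, camera adjusted p = 0.0301), with Junb at 1411 ± 191 against 1794 ± 313, while Npas4 was at 538 ± 71.8 against 436 ± 68.2 (SD, n = 5 each). Presynaptic genes were lower in 32 of 40 (median -0.078, camera adjusted p = 0.0384), a direction that the camera test turned with quantile normalization (adjusted p = 0.818) and without libraries beyond 2 SD (adjusted p = 0.509). That call also ended with a common library total (adjusted p = 0.136) and a filter at 50 (adjusted p = 0.0933), and the immediate-early call with a filter at 50 (adjusted p = 0.0663) and without libraries beyond 2 SD (adjusted p = 0.0679). Autism-risk chromatin genes were higher in 37 of 50 cases, with a median of 0.085 and a camera adjusted p of 6.26e-04. Without libraries beyond 2 SD their median was 0.039 (camera adjusted p = 0.0365). Kmt2a, a histone methyltransferase, was at 5593 ± 1543 against 3990 ± 213 (SD, n = 5 each). Voltage-gated ion channel genes were higher in 35 of 52 (median 0.065, camera adjusted p = 0.00536), with the calcium channel gene Cacna1h at 2301 ± 668 against 1545 ± 165 (SD, n = 5 each). Olfactory bulb genes were higher in 11 of 14 (median 0.17, camera adjusted p = 0.0301), and adjusted over the list alone Cdhr1 rose (log2 difference 0.48) and Penk fell (-0.30). In the immediate-early, presynaptic, chromatin, channel and microglia lists 0 genes passed adjusted over the list alone, and 0 over all genes in any list. Leaving out 1 library ended 5 of the 9 calls. The P21 immediate-early call ended without heterozygote-labelled replicate 1 or 4 or wild-type replicate 4 (adjusted p up to 0.0913, medians -0.14, -0.14 and -0.11), and the presynaptic one without heterozygote-labelled replicate 3 or 4 or wild-type replicate 5 (up to 0.479, medians -0.033, -0.095 and -0.035). The olfactory bulb call ended without heterozygote-labelled replicate 1, 4 or 5 or wild-type replicate 1 or 3 (up to 0.154, medians 0.19, 0.18, 0.14, 0.14 and 0.097). The microglial call ended without heterozygote-labelled replicate 3 (adjusted p = 0.0866) and the ion channel call without wild-type replicate 2 (adjusted p = 0.0913).

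Medians at P21 also moved by more than 1.5 times with 1 library left out. Without heterozygote-labelled replicate 2 they were -0.52 for blood and 0.053 for chromatin genes, and without replicate 3 -0.53 for blood, -0.10 for microglia, -0.091 for immediate-early and -0.033 for presynaptic genes. The ion channel median was 0.10 without heterozygote-labelled replicate 4, 0.037 without replicate 5 and 0.027 without wild-type replicate 2. Without wild-type replicate 5 microglial genes were at -0.28 and presynaptic genes at -0.035, and without wild-type replicate 3 olfactory bulb genes were at 0.097.

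The descriptions of the P21 samples carry a prefix of 11, 16 or 24 whose meaning is not given. Prefix 11 holds 2 samples per genotype, prefix 24 holds 3 heterozygote-labelled and 1 wild-type, and prefix 16 holds 2 wild-type samples only. Within prefix 11 the ribosomal list differed by -0.097 and the oxidative phosphorylation list by -0.12 on the log2 scale, and within prefix 24 by -0.24 and -0.21. The blood list differed by -0.21 within prefix 11 and by -0.14 within prefix 24. The microglial list differed by 0.18 within prefix 11 and by -0.36 within prefix 24. With the prefix as a block the microglial, blood and ion channel lists lost their calls, with adjusted p values of 0.514, 0.0717 and 0.234. With the trend on gene length removed the chromatin, ion channel and immediate-early lists lost theirs, with 0.851, 0.437 and 0.0623 and medians of 0.010, 0.027 and -0.087, and the microglial median was -0.083 (adjusted p = 0.0492). Of 100 splits of the P21 libraries 70 called at least as many lists as the 9 called here.

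Gene by gene, limma called 0 of 17157 genes at P21, while 2531 had an unadjusted p below 0.05 and chance gives 858 on average. Genes are not independent, so such a count can lie far from its average by chance, and it was not computed in the splits. Limma with library quality weights called 1, limma without the trend called 0, and a fit of all 36 libraries together called 43, with 39 higher and 4 lower. In that joint fit Ermard, Nfxl1, Col5a1 and Trim7 passed, with adjusted p values of 0.0195, 0.0389, 0.0295 and 0.0132. Trim7 was at 69.3 ± 4.80 against 44.7 ± 3.11 and Ermard at 477 ± 54.3 against 306 ± 46.9 (SD, n = 5 each). The collagen gene Col5a1 was at 1083 ± 331 against 614 ± 99.1 (SD, n = 5 each). With Col6a1, at 2187 ± 580 against 1468 ± 146, it passed adjusted over the fibroblast and meninges list alone. The other named genes were Myom1, Bbs2 and Plekha7, with log2 differences of 0.85, 0.44 and 0.36, and Nwd2, Babam2 and Tmsb10, with -0.29, -0.40 and -0.30, all at an adjusted p of 0.303.

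In young adult brains at P56, the oligodendrocyte, precursor and astrocyte lists were called higher in the heterozygote-labelled libraries with the preset correlation and not with an estimated one. Microglial genes were higher in 17 of 25 cases and not called (median 0.050, camera adjusted p = 0.107). Myelin and oligodendrocyte genes were higher in 25 of 25 cases, with a median log2 difference of 0.19. Myrf, the transcription factor that drives myelin genes, was at 2949 ± 349 against 2328 ± 353, and Ugt8a, an enzyme of myelin lipid synthesis, at 3124 ± 284 against 2479 ± 470 (SD, n = 5 each). Oligodendrocyte precursor genes were higher in 14 of 15 cases, with a median of 0.18, including the growth factor receptor gene Pdgfra at 1577 ± 168 against 1280 ± 144 (SD, n = 5 each). Astrocyte genes were higher in 23 of 25, with a median of 0.14, and the glutamate transporter gene Slc1a2, at 54373 ± 5614 against 42525 ± 2035 (SD, n = 5 each), rose adjusted over the list alone (adjusted p = 0.0141). Camera adjusted p values were 3.39e-07 for myelin, 2.16e-04 for precursors and 1.22e-04 for astrocytes. They were adjusted p = 0.791, 0.424 and 0.791 with an estimated correlation, and the lists' mean log2 values per library gave exact two-sided permutation p values of 0.278, 0.0238 and 0.460, not adjusted for the number of lists. These differences rest in large part on P56 wild-type replicate 3, without which the medians were 0.075 for myelin, 0.097 for precursors and -0.015 for astrocytes (adjusted p = 0.0150, 0.0136 and 0.376). Without wild-type replicate 2 the myelin and astrocyte medians were 0.32 and 0.26, and without heterozygote-labelled replicate 5 they were 0.12 and 0.076. The astrocyte median was 0.22 without heterozygote-labelled replicate 3 and 0.24 without wild-type replicate 4.

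Another 9 lists were called at P56 with the preset correlation, and with an estimated correlation their adjusted p values were 0.791 to 0.880. Their mean log2 values per library gave exact two-sided permutation p values of 0.103 to 0.563. Higher were autism-risk chromatin genes in 42 of 50 cases (median 0.11, camera adjusted p = 3.95e-07), with the cohesin loader gene Nipbl at 1920 ± 168 against 1627 ± 178 (SD, n = 5 each). Thalamus and habenula genes were higher in 18 of 19 (median 0.14, camera adjusted p = 0.00269), with Plekhg1 at 1663 ± 198 against 1267 ± 260 (SD, n = 5 each). Fibroblast and meninges genes were higher in 18 of 24 (median 0.098, camera adjusted p = 0.0332). Oxidative phosphorylation genes were lower in 73 of 74 cases (median -0.15, camera adjusted p = 2.23e-09) and ribosomal protein genes in 78 of 79 (median -0.14, camera adjusted p = 2.16e-04). With the trend on gene length removed their medians were -0.068 and -0.060. The ribosomal call ended without P56 heterozygote-labelled replicate 3 or wild-type replicate 2 or 4 (adjusted p up to 0.749, without wild-type replicate 2). Immediate-early genes were lower in 21 of 24 (median -0.24, camera adjusted p = 6.03e-05), with the activity-dependent gene Npas4 at 519 ± 104 against 749 ± 230 (SD, n = 5 each). Blood cell genes were lower in 10 of 11 (median -0.39, camera adjusted p = 0.00348), with Hbb-bs at 3384 ± 308 against 4567 ± 1384 (SD, n = 5 each). Presynaptic genes were lower in 27 of 40 (median -0.044) and unfolded protein and heat shock genes in 23 of 25 (median -0.068), both at a camera adjusted p of 0.0454. With quantile normalization the presynaptic median was 0.0064 (adjusted p = 0.841), and that call also ended with a common library total (adjusted p = 0.0842), a filter at 50 (adjusted p = 0.0658) and the replicate block (adjusted p = 0.0563). The heat shock call ended with quantile normalization (adjusted p = 0.139) and a filter at 50 (adjusted p = 0.0524).

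Several of these P56 calls rest on wild-type replicate 3. Without it the thalamus, immediate-early, fibroblast and presynaptic calls ended, with adjusted p values of 0.221, 0.0616, 0.725 and 0.684. The fibroblast call also ended without heterozygote-labelled replicate 3 or 5 or wild-type replicate 2, and the presynaptic one without heterozygote-labelled replicate 2, 4 or 5 or wild-type replicate 5. The heat shock call ended without heterozygote-labelled replicate 2, 3 or 4 or wild-type replicate 3 or 4 (adjusted p up to 0.881, without wild-type replicate 4), and the blood call without wild-type replicate 5 (adjusted p = 0.0505). Without wild-type replicates 2, 3 and 4 in turn the oxidative phosphorylation median was -0.078, -0.22 and -0.089 and the ribosomal one -0.016, -0.27 and -0.041. The ribosomal median was -0.074 without heterozygote-labelled replicate 3 and -0.20 without replicate 5. Without wild-type replicate 3 the thalamus, immediate-early, fibroblast and presynaptic medians were 0.078, -0.12, -0.0048 and 0.0029. The presynaptic median was -0.080 without heterozygote-labelled replicate 3, -0.077 without wild-type replicate 2 and -0.071 without replicate 4. The fibroblast median was 0.15 without heterozygote-labelled replicate 2 and 0.024 without replicate 5. The heat shock median was -0.11 without heterozygote-labelled replicate 5, -0.15 without wild-type replicate 1 and -0.015 without wild-type replicate 4. The blood median was -0.25 without wild-type replicate 4 and -0.23 without replicate 5, and the chromatin one 0.068 without wild-type replicate 2.

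Slc1a2 among astrocyte genes and Ptprz1 among progenitor genes (log2 difference 0.43) were the only members of any list that passed adjusted over the list alone at P56, and 0 did over all genes. With the trend on gene length removed the chromatin and heat shock lists lost their calls, with adjusted p values of 0.0582 and 0.299 and medians of 0.021 and -0.026. Of 100 splits of the P56 libraries 66 called at least as many lists as the 12 called here.

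**Figure D2:**
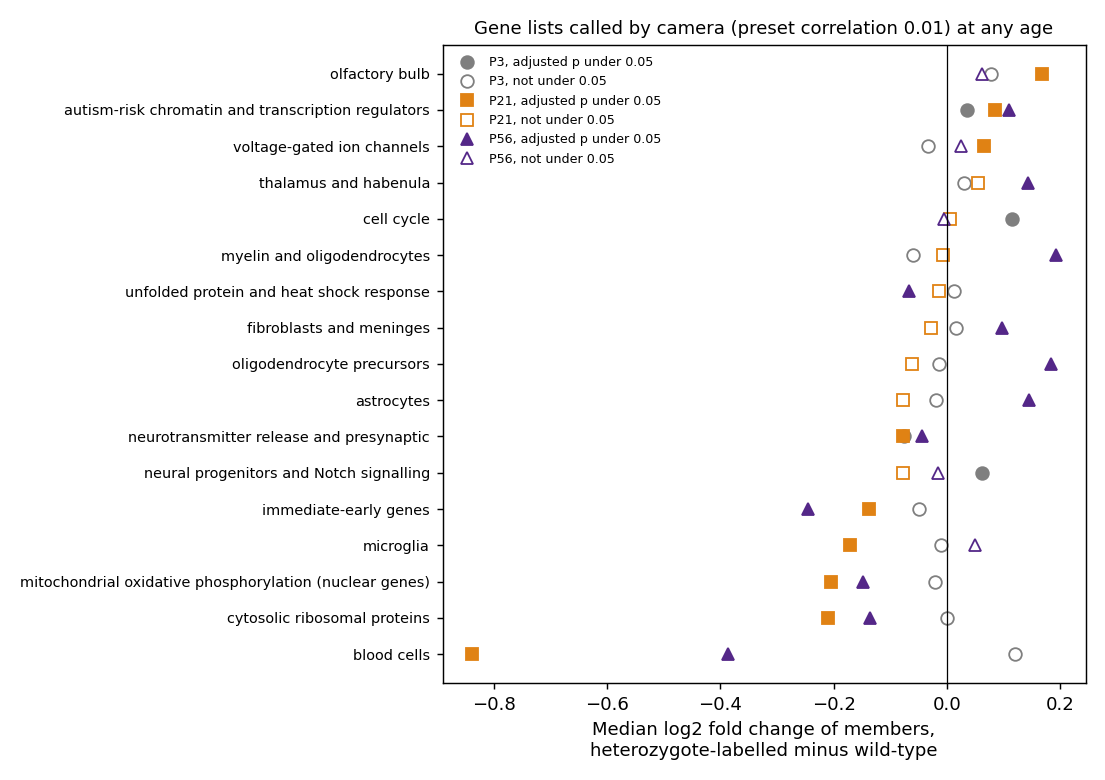
Median log2 fold change of the members of each gene list (horizontal axis, heterozygote-labelled minus wild-type) for the lists called at any age with the preset correlation, with 1 symbol per age. Filled symbols mark a camera adjusted p under 0.05. The largest difference is that of blood cell genes at P21, at -0.84 (-0.38 with the description prefix as a block), and with an estimated correlation only the progenitor list at P3 was called.

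Gene by gene, limma called 0 of 17310 genes at P56, while 1313 had an unadjusted p below 0.05 and chance gives 866 on average, with the same limit as at P21. Limma with library quality weights also called 0, and limma without the trend and the joint fit of all libraries each called 1. The smallest p belonged to Mlxipl, a glucose-responsive transcription factor, at 88.6 ± 7.90 against 45.5 ± 5.40 (SD, n = 5 each). Its log2 difference was 0.95 (SE 0.139) with an adjusted p of 0.178, and 0.0283 in limma without the trend. Dock10 was at 2111 ± 120 against 1609 ± 77.9, the transporter gene Abca9 at 450 ± 12.5 against 321 ± 22.8, and Slc7a11, the cystine-glutamate exchanger, at 1411 ± 61.2 against 1095 ± 56.9 (SD, n = 5 each). The genotype ranges of these 4 genes did not overlap, and their adjusted p values were 0.178 to 0.241. The other named genes were Tead1, Zbtb20 and Slc7a2, with log2 differences of 0.40, 0.60 and 0.42, and Ly6e, Rwdd2a and Amn, with -0.29, -0.33 and -0.68.

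**Figure D3:**
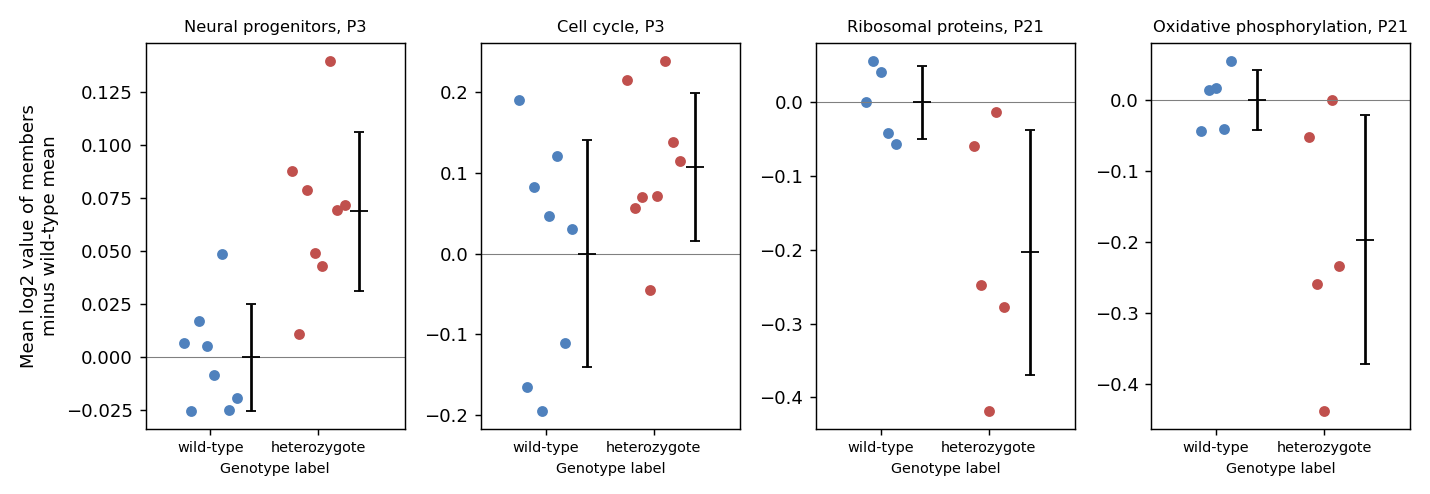
Mean log2 value of a list's members per library minus the wild-type mean (vertical axis), by genotype label, for 2 lists at P3 and 2 at P21. Points are libraries and bars are the mean ± SD of 8 libraries per group at P3 and 5 at P21. At P21 the heterozygote-labelled libraries spread from -0.42 to -0.014 for ribosomal proteins and the wild-type ones from -0.056 to 0.056.

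Whether the genotype difference itself changed with age was tested by interaction in a fit of all libraries. The Myt1l contrast of P21 minus P3 was -0.37 on the log2 scale (SE 0.103, unadjusted p = 8.53e-04, adjusted p = 0.801). From P3 to P56 the contrast was -0.35 (adjusted p = 0.904) and from P21 to P56 it was 0.022 (adjusted p = 1.000). Limma called 0 of 18840 genes from P3 to P21, with 1097 at an unadjusted p below 0.05, and 0 from P3 to P56, with 863. From P21 to P56 it called 1, the predicted gene Gm31513, with a contrast of -2.82 (SE 0.491, adjusted p = 0.0282), chosen after its values were seen. Its mean was 9.46 normalized counts. Among the lists, camera called 6 contrasts from P3 to P21, 7 from P21 to P56 and 9 from P3 to P56. From P3 to P21 the oxidative phosphorylation contrast was -0.18 (adjusted p = 5.79e-17) and the ribosomal one -0.21 (adjusted p = 7.10e-16). From P21 to P56 astrocyte genes had a contrast of 0.24 (adjusted p = 1.34e-05) and microglial genes one of 0.22 (adjusted p = 1.65e-05). With an estimated correlation 0 lists were called in each contrast, with lowest adjusted p values of 0.988, 0.812 and 0.882.

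Across genes, the genotype differences of the ages, which share no library, had Spearman correlations of 0.323 for P3 and P21, 0.266 for P3 and P56 and 0.442 for P21 and P56. Genes are not independent replicates, so no p is given. Of the genes with an unadjusted p below 0.05, 129 were higher at both P21 and P56 where chance gives 45.8, and 174 were lower at both where chance gives 50.3 for independent genes. Genes are not independent here, and the difference follows exonic length at P21 and P56 alike (Spearman 0.291 and 0.301). This may add to such agreement, which was not recomputed with the length trend removed.

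Sets of genes that rise or fall with age in wild-type brains were tested for a lean of the heterozygote-labelled profile to younger or older brains. Each set came from wild-type libraries of the other ages. The sets tested at P3 thus rest on the change from P21 to P56. For some lists, such as myelin, that change ran against the one from P3 to P21. The P3 result therefore does not measure a lean to a younger or older brain around P3. At P3 the genes that rise from P21 to P56 had a median log2 difference of 0.050 in 257 genes (camera adjusted p = 5.47e-04, and adjusted p = 0.255 with an estimated correlation). The genes that fall had a median of -0.0063 in 286 genes (adjusted p = 0.822). At P21 the medians were -0.0049 for rising genes (adjusted p = 0.601) and 0.0030 for falling genes (adjusted p = 0.534). At P56 the rising genes had a median of 0.038 (adjusted p = 0.563) and the falling genes one of 0.093 in 170 genes (camera adjusted p = 0.0129, and adjusted p = 0.119 with an estimated correlation). The P3 call for rising genes ended without P3 wild-type replicate 1 (adjusted p = 0.0857), and the P56 call for falling genes without P56 heterozygote-labelled replicate 2 (adjusted p = 0.0595).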

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

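The tests of exchanged labels and of neighbouring genes, and the alternatives without libraries beyond 2 SD, without the P3 libraries numbered 1 to 3 and with the length trend removed, were chosen after the results were seen. Among 140 groups searched for a library far from the rest, 6 had one, and chance gives about 1 in 20 groups, or 7.

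The Myt1l value of P56 wild-type replicate 3, 8115 normalized counts, lay far above the 5181 to 5983 of the others, with a gap of 0.727 of the group's range. P3 heterozygote-labelled replicate 7 had 18966 genes above 0 against 19015 to 19045 in the others, a gap of 0.620 of the range. The presynaptic list's mean log2 value in P3 heterozygote-labelled replicate 1 was 13.0 against 12.7 to 12.8, a gap of 0.594. The microglial list's mean in P21 wild-type replicate 5 was 8.83 against 9.29 to 9.40, a gap of 0.802. Bbs2 in P21 wild-type replicate 2 was 727 against 511 to 560, a gap of 0.775. The myelin list's mean in P56 heterozygote-labelled replicate 5 was 12.6 against 12.2 to 12.3, a gap of 0.756. The genotype difference of Gm31513 differed between P21 and P56 by an interaction test, with a log2 contrast of -2.82 (limma adjusted p = 0.0282).

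Myt1l was higher, not lower, in the P3 libraries labelled heterozygote, which goes against a plain loss of transcript. An exchange of 1 or 2 labels is argued against because 0 of 16 libraries lay inside the other genotype's range, while an exchange of all labels of the age was not tested. An effect shared by the neighbourhood is argued against because the 22 tested genes within 2 Mb had a median log2 difference of -0.024 (SE 0.041). Single genes ran from -0.39 to 0.28, and 0 had an unadjusted limma p below 0.05. A median cannot exclude an effect on a single neighbour. A younger profile is argued against by 1338 genes that fall from P3 to P21 in heterozygote-labelled libraries about as Myt1l does there (-1.02 on the log2 scale). Their median P3 difference was 0.019, with a 95th percentile of bootstrap medians of 0.025, far from the 0.48 of Myt1l. The P3 heterozygote-labelled libraries served both to choose these genes and to give the difference, which favours a younger profile. The bootstrap drew genes, so it does not measure the spread between mice. An effect of the mutated allele on its own transcript may account for the difference and stays untested, since the labels give no allele.

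Ribosomal and oxidative phosphorylation genes were lower at P21 and P56. At P21 gene length and level as the whole cause are argued against, since the list medians lay at percentile 0 of sets matched on both for each list, although those sets had medians of -0.16 and -0.17, removing the length trend took the list medians from -0.21 and -0.20 to -0.12 and -0.097, and the percentile may overstate the separation because the members are correlated (0.718 and 0.799). There the spread between libraries cannot be told apart from a difference, since the exact permutation p of 0.0317 for each list is not adjusted for the 29 lists, which the bound set beforehand left out of account, and fry adjusted over the lists gave 0.404 for both. At P56 the ribosomal median lay at percentile 9.5 of matched sets and the oxidative phosphorylation one at percentile 0.2, with exact permutation p values of 0.563 and 0.278, so length could account for the former, and the spread between libraries for both. A difference between the genotypes stays open as untested, and so does RNA quality, which no file gives.

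At P3 cell cycle and progenitor genes lay higher and presynaptic genes lower. The spread between libraries could account for the cell cycle list (exact permutation p = 0.0923) and the presynaptic list (exact permutation p = 0.273), and is argued against for the progenitor list (exact permutation p = 0.00109, fry adjusted p = 0.0392). The P3 library beyond 2 SD, wild-type replicate 1, as the whole cause is argued against by the medians of the cell cycle and progenitor lists. These medians went from 0.11 and 0.063 to 0.16 and 0.058 without it (camera adjusted p = 7.43e-15 and 1.37e-04). The presynaptic median went from -0.076 to -0.040 without it (camera adjusted p = 0.00231). It was -0.027 (camera adjusted p = 0.0161) without the libraries with description numbers 1 to 3. Camera at the preset correlation called at least 4 lists in 95 of 100 splits at P3. Its p values therefore decide this for none of these lists, and whether such libraries account for the presynaptic difference stays open. A younger profile predicts lower values of genes that rise with age, but the sets tested at P3 cannot decide this. They rest on the change from P21 to P56, which for some lists, such as myelin, ran against that from P3 to P21. The rising genes lay higher (limma's camera p = 2.74e-04, and p = 0.127 with an estimated correlation), while the falling ones went both ways (camera p = 0.948). The median of the falling genes was near 0. Whether a younger profile accounts for these lists stays open. A difference in the share of dividing cells between the genotypes stays open as untested.

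Splits of the libraries into groups of the real sizes, 100 per comparison with the real one included, tested whether chance can be excluded. For the 1 gene at P3, 4 splits gave as many, just under the bound set beforehand, with 2 as the highest other. That result is not adjusted for the number of comparisons split, so it does not exclude chance by itself. For the 4 lists at P3 chance was not excluded, with 95 splits as high and 20 lists in the highest other. It was not for the 9 lists at P21 (70 splits, highest other 18) or the 12 at P56 (66 splits, highest other 21). A count of 0 is reached by all 100 splits, with highest other counts of 1 gene at P21, 250 at P56, 3 for the interaction from P3 to P21 and 534 from P3 to P56. For the 1 gene of the interaction from P21 to P56 chance was not excluded (30 splits, highest other 1234). Splits that call 250, 534 or 1234 genes point to a structure of the samples, and what these splits share was not tested. For the wild-type ages chance was excluded, with 1 split as high in each case, 14064 genes against 9685 in the highest other from P3 to P21 and 1688 against 43 from P21 to P56.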

How the results depend on the processing

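Alternatives without libraries beyond 2 SD, without the P3 libraries numbered 1 to 3, with the length trend removed and with the prefix block in list tests were chosen after the data were seen. Besides left-out libraries, 153 of 176 alternative values of the main results were labelled unchanged, and so were 363 of 369 of the named genes other than Myt1l. None of these genes passed in the main fit. A gene that again did not pass was labelled unchanged whatever its size or sign, so this tally does not show that the differences were stable. Dock10 at P56 was labelled so at 0.39 and at 0.28 with the length trend removed. Of the called lists 154 of 201 kept their direction and call. A changed count could still be labelled unchanged, such as 12 lists against 9 at P21 without libraries beyond 2 SD. So could a set that passed in neither setting while its median changed sign. The P21 rising set did so, at -0.0049 and at 0.039 with the length trend removed. With 1 library left out, 233 of 274 values of called lists kept their direction and call, 40 lost their call and 1 turned. The causes of the changes below were not tested. P56 has no library beyond 2 SD, so that alternative was not run for its genes and lists.

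Limma without the trend called 2 genes at P3 and 1 at P56, library quality weights and an added value of 8 each called 1 at P21, and the fit of all libraries called 43 at P21 and 1 at P56. The interaction from P21 to P56 called 0 with quantile normalization, with a filter at 50 and with quality weights, and the wild-type change from P21 to P56 called 2999 with quality weights. With an estimated correlation 1, 0 and 0 lists were called at P3, P21 and P56, and without the P3 libraries numbered 1 to 3 there were 8 at P3.

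The median of the rising set at P3 was 0.026 without libraries beyond 2 SD (adjusted p = 0.0551), 0.050 with an estimated correlation (adjusted p = 0.255) and 9.06e-04 with sets of 1000 genes (adjusted p = 0.463). That of the falling set at P3 was 0.024 without libraries beyond 2 SD (adjusted p = 0.0316), and with 1000 genes the test turned, at -0.022 (adjusted p = 0.0285). At P56 the falling set was at 0.053 with quantile normalization (adjusted p = 0.101) and 0.093 with an estimated correlation (adjusted p = 0.119), and the rising set at 0.085 with the length trend removed (adjusted p = 0.0105) and 0.13 with sets of 100 genes (adjusted p = 0.0159). Presynaptic genes at P21 turned in the test, at -0.0044 with quantile normalization and 0.0050 without libraries beyond 2 SD, and heat shock genes at P56 at -0.015 without wild-type replicate 4 (-0.15 without wild-type replicate 1).

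With each library left out in turn, counts of genes ran from 1 to 1 at P3, 0 to 1 at P21 and 0 to 1 at P56, where heterozygote-labelled replicates 4 (P21) and 5 (P56) gave the 1. Interaction counts ran from 0 to 1 from P3 to P21 (1 without replicate 5 of either P21 group), 0 to 4 from P21 to P56 (changed by 16 of 36 libraries) and 0 to 0 from P3 to P56. The wild-type P21 against P3 count of genes ran from 13756 to 14152, and the wild-type P56 against P21 count of genes from 874 to 2315, with 1014, 998, 874 and 967 without P21 replicates 1 to 4 and 1084 without P56 replicate 5. Lists called ran from 3 to 8 at P3 (8 without heterozygote-labelled replicate 1), 7 to 14 at P21 (14 without wild-type replicate 5) and 8 to 15 at P56. The log2 difference of Myt1l ran from 0.46 to 0.50 at P3, 0.060 to 0.14 at P21 and 0.075 to 0.24 at P56. Rising sets ran from 0.023 (P3 wild-type replicate 1, adjusted p = 0.0857) to 0.071 at P3, -0.066 to 0.015 at P21 and -0.047 to 0.12 (P56 wild-type replicate 2, adjusted p = 0.0329) at P56. Falling sets ran from -0.027 to 0.021 at P3, -0.038 to 0.031 at P21 and 0.064 to 0.14 at P56, where heterozygote-labelled replicate 2 ended the call at 0.078 (adjusted p = 0.0595).

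With the replicate number as a block, limma called 1, 0 and 0 genes at P3, P21 and P56, and camera called 6, 10 and 12 lists. Of the pairs with the same number, 2 of 8, 2 of 5 and 1 of 5 had a correlation of residuals above 0.1. At P3 this correlation averaged 0.10 in such pairs and -0.014 in others. There 3 of 8 heterozygote-labelled libraries correlated best with their own number, so a pairing by number cannot be excluded at P3. At P21 and P56 the averages were 0.0075 and 0.024 in such pairs and -0.0021 and -0.0065 in others. The depth of sequencing is unknown, so its limit on these results cannot be given.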

Other observations

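The comparison of the P3 libraries by description number and the relation to gene length were chosen after the data were seen. Several cell types showed no call between the genotypes at any age. Endothelial and pericyte genes had median log2 differences of -0.034 at P3, -0.0097 at P21 and 0.051 at P56, with camera adjusted p values of 0.709, 0.897 and 0.586. Striatal projection neuron genes had medians of -0.062, -0.039 and 0.032 (adjusted p = 0.162, 0.897 and 0.840), and GABAergic genes -0.012, -0.023 and -0.031 (adjusted p = 0.505, 0.656 and 0.4665). Choroid plexus genes at P21 were higher in 18 of 22 cases with a median of 0.15 and did not pass (adjusted p = 0.0752). The repressor partners of REST, a factor that silences neuronal genes, had medians of 0.031, 0.018 and 0.068 (adjusted p = 0.149, 0.801 and 0.214). The relatives of Myt1l were too few for a list test. Myt1 was at 1197 ± 90.9 against 1199 ± 104 normalized counts at P3 (SD, n = 8 each), and St18 was at 520 ± 109 against 502 ± 129 (SD, n = 8 each).

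In the P3 samples the number at the end of the description ran from 1 to 42, with a meaning that is not given. Numbers 1, 2 and 3, which are wild-type replicates 1 and 2 and heterozygote-labelled replicate 1, had values of -45.0, -29.3 and -21.0 on principal component 1, and the other 13 libraries lay between -5.12 and 13.1. Across genes, the genotype difference had a Spearman correlation with exonic length of 0.0783 at P3, 0.291 at P21 and 0.301 at P56, and genes are not independent replicates.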
